A study of Mus musculus with 33 samples.

How the data were processed

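Right-lung total RNA was counted with an nCounter panel of 773 mouse genes and 12 reference genes in 33 samples, 24 taken at day 97 (6 groups of 4) and 9 taken 3 h after the dose (3 groups of 3). The groups, sexes and times were taken from the labels. Each table of normalized log2 counts was deposited by the authors with a block of linear values that equals the log2 block raised back, and only the log2 block was tested. The labels name no software, no background treatment and no choice of reference genes. From the deposited values, the log2 tables were found scaled to 6 of the reference genes (Nmt1, Oaz1, Hprt, Tbp, Abcf1 and Mrps7), whose mean log2 level was the same in every day 97 lung. The linear signal values that the authors deposited in the series matrix were found scaled to all 12, and were used for the day 97 samples as an alternative only. At 3 h, 760 rows of that matrix held the values of some gene of the log2 table and 0 of these stood under that gene's own identifier, so its 9 columns were not used.

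Raw counts were recovered from the linear values as whole multiples of a factor per sample, and gave the depth and the number of genes under 20 counts that the report states. The 8 dimmest control probes of the series matrix, whole counts not scaled there, gave a background for each day 97 lung, a step chosen after seeing the data, and no background was set at 3 h. The tests were run on the values as deposited, those at background included. On simulated data of the day 97 design with 200 of 773 genes changed, the fit of AAV-hSPB repeat against single dose recovered 46.7% of changes of 0.5 log2 units, 79.6% of 1 and 95.9% of 2, with 4% of calls false. For the 3 h design 41.7%, 79.8% and 96% were recovered, with 3.7% of calls false. Of lists without any change 7.1% had p under 0.05 in the list test.

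All groups of a table were fitted together by limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on the authors' log2 values without a filter or covariate, with 18 residual degrees of freedom at day 97 and 6 at 3 h. The p-values of each of 14 comparisons were adjusted over the 773 genes by the method of Benjamini and Hochberg, with a threshold of 0.05. The 9 comparisons between 2 groups at day 97, that of both single-dose groups with the off-doxycycline group, the interaction of dose and vector, and the 3 h comparisons were tested within their own table. Values with ± give a standard error from limma unless SD is named. Of 25 gene lists, 20 had at least 5 measured members and were tested by fry of limma, adjusted over the 20 lists, and by camera with an estimated correlation as an alternative. Fry asks whether the members change on balance, and camera whether they change more than the other genes of the panel. A p given with an estimated correlation is that of camera, so it answers another question than that of fry. The 5 lists with too few members were not tested. The count adjusted over the list alone adjusts the limma p-values of the members among themselves. Mean list levels per lung were compared by exact permutation over 70 arrangements where 4 lungs met 4. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

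The groups, comparisons, tests, gene lists, gene naming rule and most alternatives were fixed before the data were examined. The rule named, per comparison, the 12 largest rises and the 12 largest falls that passed, up to 4 members with the smallest p of each list that passed, the 3 genes with the smallest p where none passed, and a fixed set of interferon, cytokine, chemokine and lymphocyte genes, from which the text takes examples. H2-Q10 and Il23a at 3 h fall outside this rule and were chosen after their values were seen, as were the genes named for the sexes, for liver and for granzymes. The alternatives fixed beforehand were scaling to the median gene or to all 12 reference genes, the series matrix values, removal of the lowest 25% of genes, sex as a covariate, a trended and robust prior variance, a fit with the compared groups alone, omission of each lung in turn, and other splits of the lungs. Chosen after seeing the data were voom on the recovered counts, omission of on-doxycycline replicate 1 together with AAV-hSPB repeat replicate 2, omission of PBS replicate 1 at 3 h, the list test with all 12 reference genes or without the first 2 of these lungs, and the low or high series of a second identifier in the authors' table as a covariate. Some genes that passed a test are not reported here by name.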

Results

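Expression of 773 mouse genes was counted by nCounter, which reads RNA molecules through hybridized fluorescent barcodes without amplification, in 33 right-lung RNA samples from CCSP-rtTA/(teto)7Sftpb/Sftpb-/- mice on the FVB/N background. These mice lack their own surfactant protein B (SP-B), which keeps air spaces open, and make it from a doxycycline-driven transgene in the airway epithelium. Sftpb itself was not analysed here. In the first experiment 24 lungs, 2 female and 2 male in each of 6 groups, were taken at day 97. An on-doxycycline group kept the transgene on, and an off-doxycycline group lost doxycycline at day 94. Groups given AAV-hSPB or AAV-hSPBTLR9i by the airway at day 0 came off doxycycline at day 7, and the repeat groups had a further dose at day 90. In the second experiment 9 lungs, 2 female and 1 male in each of 3 groups, were taken 3 h after PBS, AAV-hSPB or AAV-hSPBTLR9i. The labels do not say that each sample came from its own animal, so p-values measure the spread between these lung samples.

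The total recovered count per lung ran from 676906 to 832041 on doxycycline, from 671453 to 749782 off it, from 622739 to 756539 after a single AAV-hSPB dose and from 597788 to 856619 after the repeat. It ran from 862348 to 980805 after a single AAV-hSPBTLR9i dose and from 851635 to 1131011 after the repeat. At 3 h it ran from 1197432 to 1490416 after PBS, from 1362535 to 1710291 after AAV-hSPB and from 1156612 to 1348095 after AAV-hSPBTLR9i. Between 65 and 117 genes per day 97 lung and between 36 and 69 per 3 h lung had fewer than 20 counts, so small changes of these genes were not detectable at this depth. Background in a day 97 lung is taken as the mean plus 2 SD of its 8 dimmest control probes. Where every lung of a group was at or below it, only a bound is given, the difference with such lungs raised to their background. Where lungs of the higher group were raised as well, that difference is not a bound.

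Lungs with repeated AAV-hSPB dosing, taken 7 days after the further dose, were compared with lungs on continued doxycycline, from which they differ in vector and in doxycycline since day 7. Genes that interferon-gamma induces rose most. Cxcl9, a chemokine that draws activated T cells, rose by 4.21 ± 0.67 log2 units (SE, n = 4 per group), with levels of 7.66 to 10.42 in the 4 repeat lungs against 3.02 to 7.07 on doxycycline, where 2 of 4 lungs were not above background and, raised to it, left 3.85 (14.4-fold). Cxcl10, its close relative, rose by 3.00 ± 0.44, and the guanylate-binding protein genes Gbp3, Gbp5 and Gbp2, which act against pathogens inside cells, rose by 1.97, 1.92 and 1.39. In this list 9 of 11 measured members rose, 9 also when adjusted over the list alone (median 1.71, limma fry adjusted p = 2.74e-06, camera adjusted p = 0.256 with an estimated correlation). Here and below, the latter p tests the members against the other genes of the panel.

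Antigen presentation rose together with these genes. Of 11 MHC class I genes 10 rose (10 adjusted over the list alone), among them the immunoproteasome subunits Psmb9 (1.44 ± 0.16) and Psmb8 (1.24 ± 0.14), the peptide transporters Tap1 (1.64 ± 0.19) and Tap2 (1.16 ± 0.14) and Nlrc5, the transcriptional activator of class I genes (1.93 ± 0.32). The remaining member, H2-Q10, a class I gene expressed mainly in liver, had a log2 change of -1.76 ± 1.01 (adjusted p = 0.206) and stood at 11.09 in 1 on-doxycycline lung with high liver transcripts. Of 10 MHC class II genes 8 rose (10 adjusted over the list alone), including H2-Eb1 (1.84 ± 0.26), H2-DMa (1.23 ± 0.15) and H2-Ab1 (1.23 ± 0.19). Both lists passed the fry test, class I with adjusted p = 2.74e-06 and class II with 7.7e-06, and each had adjusted p = 0.256 with an estimated correlation.

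The broader list of interferon-stimulated genes rose less evenly. Of 34 measured members 17 rose and 1 fell (21 adjusted over the list alone, median 0.45, adjusted p = 8.39e-05, adjusted p = 0.333 with an estimated correlation). Zbp1, a sensor of unusual nucleic acids that is also counted in the sensing and the cell death lists, rose by 2.39 ± 0.27, Mx1 by 1.53 ± 0.30 and Isg15 by 1.14 ± 0.26, whereas Ifit1 had a log2 difference of -0.07 ± 0.22 (adjusted p = 0.833). Of the interferons, Ifnb1 was not above background in any of these lungs (adjusted p = 0.393), and Ifng, not above it in the 4 on-doxycycline lungs, did not pass (adjusted p = 0.351). Without AAV-hSPB repeat replicate 2 Ifng passed (adjusted p = 0.000253). Tlr9, the receptor for unmethylated CpG DNA, rose by 0.94 ± 0.28 (adjusted p = 0.0195), a call lost when each lung was scaled to its median gene (0.71, adjusted p = 0.0538) and without on-doxycycline replicates 2 or 4 or AAV-hSPB repeat replicate 4 (adjusted p = 0.0551, 0.0775 and 0.0785).

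Part of the lymphocyte genes rose against continued doxycycline. Of 22 T cell genes 9 rose (9 adjusted over the list alone, median 0.57, adjusted p = 0.00667, adjusted p = 0.596 with an estimated correlation), with the costimulatory receptors Cd28 (1.22 ± 0.18) and Icos (0.96 ± 0.23) among them. The regulatory T cell factor Foxp3 rose by 1.41 ± 0.43, a call lost without on-doxycycline replicates 2 or 4 or AAV-hSPB repeat replicate 2 (adjusted p = 0.0636, 0.0629 and 0.0759). Of 10 checkpoint genes, which restrain T cells, 7 rose (7 adjusted over the list alone, median 1.26, adjusted p = 8.39e-05, adjusted p = 0.32 with an estimated correlation), among them Tigit (2.29 ± 0.40), Ctla4 (1.66 ± 0.35), Lag3 (1.25 ± 0.27) and Cd274, which encodes PD-L1 (1.14 ± 0.21). Cd274 and Ido1 of this list are also counted in the interferon-gamma-inducible list, so the lists are not independent. Of 11 B and plasma cell genes 6 rose (7 adjusted over the list alone, median 1.13, adjusted p = 0.00168, adjusted p = 0.386 with an estimated correlation), including the plasma cell receptor Tnfrsf17 and the B cell receptor component Cd79a (1.46 ± 0.30). Tnfrsf17 was not above background in the 4 on-doxycycline lungs or in 1 of 4 repeat lungs. With these raised to background its difference was 0.69, which is not a bound. In the list of CD8 T, NK and cytotoxic cells 5 of 22 members rose (5 adjusted over the list alone, adjusted p = 0.0214, adjusted p = 0.758 with an estimated correlation), with Xcl1 at 1.41 ± 0.27 and Cd8a at 1.32 ± 0.38, while the killing enzyme Gzmb had 0.43 ± 0.49 (adjusted p = 0.554). The Cd8a call was lost without on-doxycycline replicate 2 (1.06, adjusted p = 0.0597), and that list's call was lost under both scalings (adjusted p = 0.122 with the median gene and 0.0876 with all 12 reference genes), without on-doxycycline replicate 4 (0.0939) and without AAV-hSPB repeat replicates 1 or 4 (0.103 and 0.0761). On-doxycycline lungs not above background numbered 1 of 4 for Tigit and Xcl1, 2 of 4 for Foxp3 and Ctla4 and 3 of 4 for Cd8a and Gzmb. With such lungs of both groups raised to background the differences were 2.29, 1.32, 1.25, 1.48, 0.57 and 0.26.

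**Figure D1:**
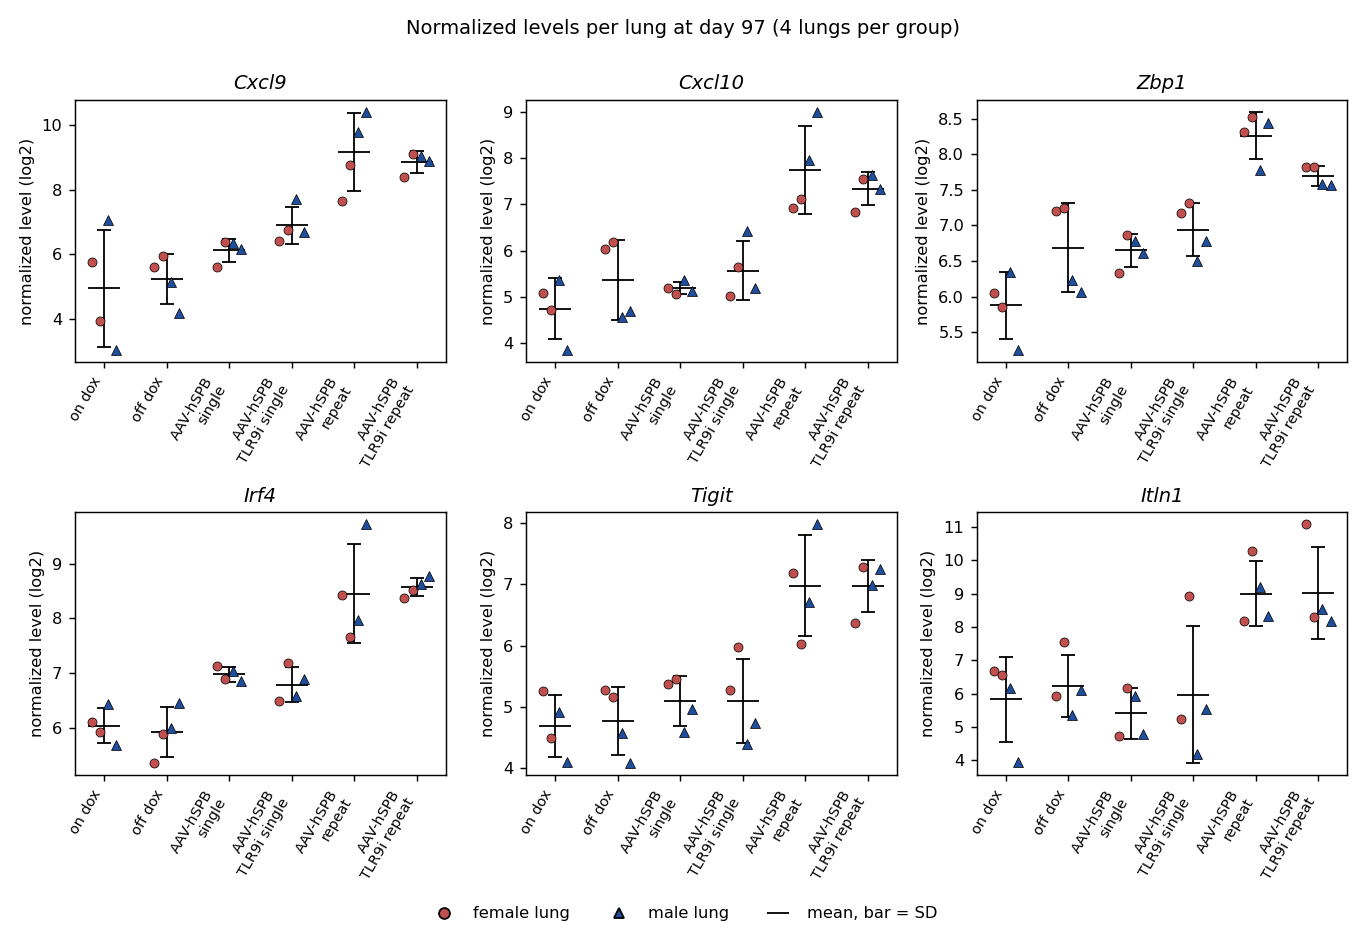
Normalized log2 levels (vertical axis) of 6 genes in each day 97 lung, by group (horizontal axis); red circles are female and blue triangles male lungs, and the bar gives the mean and SD of 4 lungs. Cxcl9 lay at 7.66 to 10.42 after the AAV-hSPB repeat dose and at 3.02 to 7.07 on doxycycline.

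Several other lists and single genes moved in the same comparison. Of 9 dendritic cell genes 2 rose and 1 fell (4 adjusted over the list alone, adjusted p = 0.00612, adjusted p = 0.716 with an estimated correlation). Of these Irf4, a factor that activated B and T cells also use, rose by 2.41 ± 0.31 and Hsd11b1, a cortisone-activating enzyme, fell by 0.99 ± 0.29, the latter call being lost without AAV-hSPB repeat replicate 2 (-0.63, adjusted p = 0.0541). Of 23 inflammasome and cell death genes 8 rose and 2 fell (12 adjusted over the list alone, adjusted p = 0.00848, adjusted p = 0.902 with an estimated correlation), with the adaptor Pycard up by 1.35 ± 0.26, the DNA sensor Aim2 up by 1.07 ± 0.19 and the cytokine gene Il18 down, with a log2 change of -0.77 ± 0.18. Of 28 nucleic acid and Toll-like receptor sensing genes 8 rose (8 adjusted over the list alone, median 0.10, adjusted p = 0.00848, adjusted p = 0.902 with an estimated correlation). Of 12 interferon and interferon receptor genes only Ifnar1 rose (0.33 ± 0.08, 1 adjusted over the list alone, list adjusted p = 0.0152, adjusted p = 0.981 with an estimated correlation and in the downward direction). The calls of the last 3 lists were lost under both scalings, with adjusted p of 0.29, 0.799 and 0.469 on the median gene and of 0.168, 0.329 and 0.804 on all 12 reference genes. Ifnar1 itself no longer passed under either (adjusted p = 0.501 and 0.0861). The interferon and receptor call was also lost without AAV-hSPB repeat replicates 1 or 4 (0.0591 and 0.0736). The chaperone genes Hspb1, Hsp90aa1 and Hsp90ab1 fell, with log2 changes of -1.19 ± 0.22, -0.67 ± 0.14 and -0.65 ± 0.15. Itln1, a lectin of mucosal epithelium, rose by 3.17 ± 0.87, which was lost without on-doxycycline replicate 4 (2.53, adjusted p = 0.0525). Ephx2, Plin4 and Mgam, genes of lipid and sugar metabolism, fell by 1.63 ± 0.59, 1.18 ± 0.39 and 1.5 ± 0.47, and all 3 calls were lost without on-doxycycline replicate 1, the lung with high liver transcripts (adjusted p = 0.184, 0.122 and 0.0958), that of Ephx2 also with the low or high series of a second lung identifier as a covariate (adjusted p = 0.0649).

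In all, limma called 180 genes higher and 23 lower of 773 (302 at an unadjusted p under 0.05) and voom on the recovered counts called 181 higher and 25 lower. The median gene was 0.15 log2 units higher under the authors' scaling, -0.07 when each lung was scaled to its median gene and 0.02 with all 12 reference genes, and the calls then split into 98 higher and 119 lower or into 114 higher and 73 lower. Calls that held under both of these scalings numbered 96 higher and 23 lower, and those that also held without each lung in turn 88 higher and 8 lower. A fit with the compared groups alone called 84 genes. AAV-hSPB repeat replicate 2 stood apart from the other lungs of its group. Its log2 levels correlated with theirs at 0.9442 to 0.9531, against 0.98 to 0.9818 among those lungs. Without it 176 genes were called higher and 14 lower. The on-doxycycline and both repeat groups lie in different blocks of the sample numbering (1 to 12 and 13 to 24), and whether these were measured in separate runs is not stated in the labels.

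Repeated AAV-hSPBTLR9i dosing was compared with continued doxycycline in the same way. Cxcl9 rose by 3.91 ± 0.67 log2 units (SE, n = 4 per group), or 3.55 with the on-doxycycline lungs raised to background, Cxcl10 by 2.59 ± 0.44 and Gbp3 by 1.43 ± 0.23, and 6 of the 11 interferon-gamma-inducible genes rose (8 adjusted over the list alone, median 1.10, adjusted p = 0.000155, adjusted p = 0.223 with an estimated correlation). Of the MHC class I genes 10 of 11 rose (10 adjusted over the list alone, adjusted p = 0.000155), Psmb9 by 1.09 ± 0.16 and Tap1 by 1.19 ± 0.19. Of the class II genes 6 of 10 rose (9 adjusted over the list alone, adjusted p = 0.000143), H2-DMa by 0.95 ± 0.15. Each MHC list had adjusted p = 0.223 with an estimated correlation. Of the checkpoint genes 5 of 10 rose (7 adjusted over the list alone, adjusted p = 0.000359, adjusted p = 0.252 with an estimated correlation), Tigit by 2.28 ± 0.40 and Lag3 by 1.30 ± 0.27. Of the B and plasma cell genes 7 of 11 rose (9 adjusted over the list alone, adjusted p = 0.00115, adjusted p = 0.265 with an estimated correlation), Tnfrsf17 by at least 0.72 (not above background in the 4 on-doxycycline lungs) and Spib, a B cell transcription factor, by 1.23 ± 0.24.

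Other genes in these lungs followed. Of the interferon-stimulated genes 5 of 34 rose (5 adjusted over the list alone, median 0.24, adjusted p = 0.00722, adjusted p = 0.549 with an estimated correlation), with Zbp1 at 1.82 ± 0.27, whereas Isg15 had 0.51 ± 0.26 (adjusted p = 0.236). This list's call was lost on the median gene (adjusted p = 0.477). Of the dendritic cell genes 1 of 9 rose, Irf4 by 2.54 ± 0.31 (2 adjusted over the list alone, adjusted p = 0.00291, adjusted p = 0.444 with an estimated correlation). Of the T cell genes 3 of 22 rose (5 adjusted over the list alone, adjusted p = 0.0308, adjusted p = 0.573 with an estimated correlation), Cd28 by 1.04 ± 0.18. Of 23 inflammasome and cell death genes 4 rose (6 adjusted over the list alone, adjusted p = 0.0236, adjusted p = 0.724 with an estimated correlation), Casp1, the protease that matures interleukin-1, by 0.85 ± 0.20. Of the 12 interferon and receptor genes 1 was called (1 adjusted over the list alone, list adjusted p = 0.00484, adjusted p = 0.724 with an estimated correlation). This was Ifna4, with means of 3.8 recovered counts on doxycycline and 13.8 after the repeat, not above background in any of these lungs, so the call is not read as a rise. The calls of the last 3 lists were lost under both scalings (adjusted p of 0.15, 0.477 and 0.89 on the median gene and of 0.115, 0.153 and 0.153 on all 12 reference genes). The T cell call was also lost without on-doxycycline replicate 4 (0.133) or AAV-hSPBTLR9i repeat replicates 2 or 4 (0.125 and 0.0727). The inflammasome call was lost without on-doxycycline replicate 4 (0.0992) or AAV-hSPBTLR9i repeat replicates 1 or 2 (0.0728 and 0.066). Hspb1 and Hsp90aa1 fell, with log2 changes of -0.93 ± 0.22 and -0.73 ± 0.14.

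Limma called 85 genes higher and 4 lower after repeated AAV-hSPBTLR9i (201 at an unadjusted p under 0.05) and voom 111. The count was 57 without on-doxycycline replicate 4 and 58 without AAV-hSPBTLR9i repeat replicate 2. On the median gene, which moved the median of all genes from 0.10 to -0.10, 53 genes were higher and 37 lower, and with all 12 reference genes 61 and 18. Calls that held under both scalings and without each lung in turn numbered 46 higher and 2 lower.

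**Figure D2:**
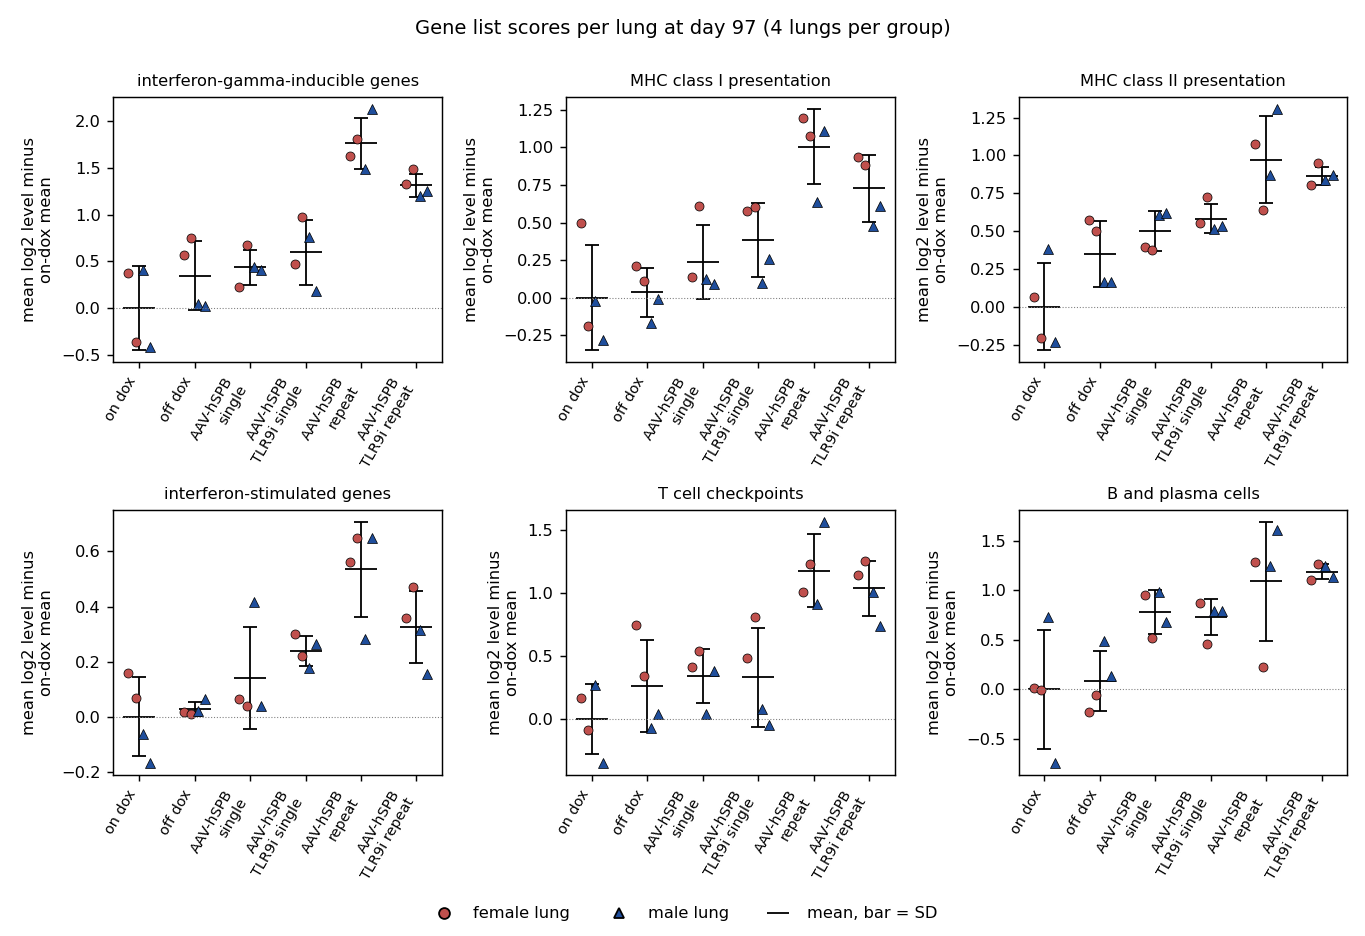
Mean log2 level over the measured genes of 6 lists in each day 97 lung, less the on-doxycycline mean (vertical axis), by group (horizontal axis); red circles are female and blue triangles male lungs, and the bar gives the mean and SD of 4 lungs. The scores of both repeat groups lie above the on-doxycycline mean in every panel, under the authors' scaling.

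The repeat dose was next compared with a single dose of the same vector. Repeat lungs were taken 7 days after their last dose and single-dose lungs 97 days after theirs. The number of doses, the time since the last dose and the airway dosing itself therefore cannot be told apart here. After AAV-hSPB, Cxcl9 was 3.04 ± 0.67 log2 units higher than after a single dose (SE, n = 4 per group, 8.2-fold) and Cxcl10 2.55 ± 0.44. Of the interferon-gamma-inducible genes 6 of 11 rose (8 adjusted over the list alone, median 1.24) and of the MHC class I genes 10 of 11 (10 adjusted over the list alone, median 0.87). Each list had fry adjusted p = 0.00024 and adjusted p = 0.168 with an estimated correlation. Tap1 rose by 1.09 ± 0.19, Psmb8 by 0.87 ± 0.14 and Zbp1 by 1.61 ± 0.27. Irf4 rose by 1.47 ± 0.31. Itln1 was 3.59 ± 0.87 higher, a call lost without AAV-hSPB single replicate 4 (3.38, adjusted p = 0.0562). Il18 fell by 0.87 ± 0.18.

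The interferon-stimulated list rose on balance between the AAV-hSPB doses (6 of 34 called, 15 adjusted over the list alone, adjusted p = 0.00467, adjusted p = 0.435 with an estimated correlation), as did the checkpoint list (2 of 10, 6 adjusted over the list alone, adjusted p = 0.00596, adjusted p = 0.435 with an estimated correlation) and the class II list (2 of 10, 3 adjusted over the list alone, adjusted p = 0.0157, adjusted p = 0.501 with an estimated correlation). With all 12 reference genes these 3 calls were lost (adjusted p = 0.053, 0.053 and 0.124). The class II call was also lost without AAV-hSPB single replicates 1 or 2 (0.0544 and 0.0542) or AAV-hSPB repeat replicates 1 or 4 (0.0514 and 0.0849). The T cell, B and plasma cell and CD8 T, NK and cytotoxic lists did not pass between the doses (adjusted p = 0.132, 0.485 and 0.504). Limma called 52 genes higher and 4 lower (168 at an unadjusted p under 0.05) and voom 52 in all. The count was 28 without AAV-hSPB single replicate 4, 37 without single replicate 3 and 34 without AAV-hSPB repeat replicate 4. With all 12 reference genes 27 were higher and 21 lower, and a fit with the compared groups alone called 12.

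After AAV-hSPBTLR9i, 3 genes were higher with the repeat than with the single dose and none was lower (60 at an unadjusted p under 0.05, 3 by voom): Irf4 (1.78 ± 0.31, adjusted p = 0.0104), Tigit (1.88 ± 0.40, adjusted p = 0.0303) and Lax1, an adaptor that dampens lymphocyte signalling (1.70 ± 0.34, adjusted p = 0.0296). The log2 difference was 1.96 ± 0.67 for Cxcl9 (adjusted p = 0.379) and 1.77 ± 0.44 for Cxcl10 (adjusted p = 0.112). None of the 20 lists passed, the smallest adjusted p being 0.0944 for the checkpoint list (median 0.78), with 0.171 for the interferon-gamma-inducible and 0.196 for the MHC class I list. Each of the 3 calls was lost without some lung, that of Irf4 without single replicates 1 or 3 or repeat replicate 4 (adjusted p = 0.0677, 0.0614 and 0.0606). The count was 0 without those lungs and 1 without single replicate 4 or repeat replicates 2 or 3. It was 1 with all 12 reference genes and 14 with the compared groups alone.

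Whether the vectors differed was tested directly at each dose. No gene differed between AAV-hSPBTLR9i and AAV-hSPB after a single dose (limma 0 of 773, 8 at an unadjusted p under 0.05, voom 0), and the list with the smallest p had adjusted p = 0.977. After the repeat dose limma called 0 genes (51 at an unadjusted p under 0.05, voom 0). The smallest p after a single dose belonged to Gca (0.36 ± 0.12), Il22ra1 (not above background in any of these lungs) and Il3ra (0.33 ± 0.14), each with adjusted p = 1, and after the repeat dose to Tap2 (-0.51 ± 0.14), Rbck1 (-0.38 ± 0.11) and Xaf1 (-0.41 ± 0.12), each with adjusted p = 0.723, and Isg15 had -0.63 ± 0.26 (adjusted p = 0.723). The interferon-gamma-inducible, MHC class I and interferon-stimulated lists had medians of -0.53, -0.36 and -0.24, each with adjusted p = 0.279. The mean of the interferon-gamma-inducible list was 0.45 lower with AAV-hSPBTLR9i, a difference of -0.45 (95% interval -0.91 to 0.02, two-sided exact permutation p = 0.0286 unadjusted, the smallest that 70 arrangements of 4 against 4 lungs allow).

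The interaction, the effect of the repeat dose with AAV-hSPBTLR9i less that with AAV-hSPB, passed for 0 genes (24 at an unadjusted p under 0.05, voom 0). The count was 1 without AAV-hSPB repeat replicate 2. Il19 (1.95 ± 0.60) and Bpi (-0.99 ± 0.32) were among the 3 genes with the smallest p, each with adjusted p = 0.995. Their group means were 4.0 to 11.5 and 12.2 to 22.0 recovered counts, where the background of the day 97 lungs ran from 12.3 to 32.7. Genes of the interaction were not set against background lung by lung, so these 2 sizes are not read as exact. The list means differed by -0.61 (95% interval -1.27 to 0.05) for the interferon-gamma-inducible genes, by -0.42 (-0.95 to 0.11) for MHC class I and by -0.31 (-0.59 to -0.03) for the interferon-stimulated genes, and each list had fry adjusted p = 0.227. The intervals of the interferon-gamma-inducible and MHC class I lists include no difference. That of the interferon-stimulated list, not adjusted for the number of lists, leaves it out. It runs from a small difference to one larger than the AAV-hSPB effect on the same list, 0.39 (0.20 to 0.59). As no list passed and the intervals are wide, the vectors were shown neither to differ nor to act alike.

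**Figure D3:**
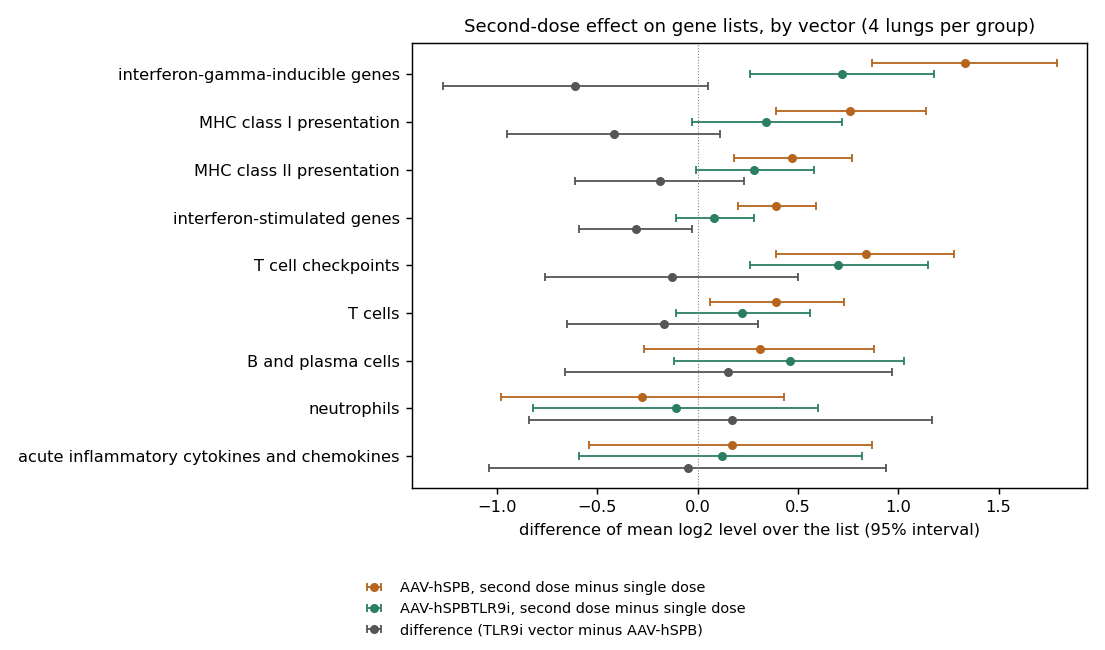
Difference of the mean log2 level of each list between repeat and single dose (horizontal axis, points with 95% intervals, 4 lungs per group), for AAV-hSPB in brown, AAV-hSPBTLR9i in green and their difference in grey. The interferon-gamma-inducible difference was 1.33 (0.87 to 1.79) with AAV-hSPB and 0.72 (0.26 to 1.18) with AAV-hSPBTLR9i, and their difference was -0.61 (-1.27 to 0.05).

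Lungs 97 days after a single dose were compared with lungs on continued doxycycline. They differ in vector and in doxycycline since day 7, and this comparison does not separate these. After AAV-hSPBTLR9i, H2-DMa, a chaperone for loading class II molecules, was 0.75 ± 0.15 log2 units higher (SE, n = 4 per group, adjusted p = 0.0342) and Psmb9 0.76 ± 0.16 (adjusted p = 0.0454), the only genes limma called (83 at an unadjusted p under 0.05, voom 3). The MHC class II list rose on balance (1 of 10 called, 4 adjusted over the list alone, median 0.65, adjusted p = 0.0103, adjusted p = 0.259 with an estimated correlation). So did the MHC class I list (1 of 11, 7 adjusted over the list alone, adjusted p = 0.0383, adjusted p = 0.392 with an estimated correlation), the interferon-gamma-inducible list (0 of 11, 4 adjusted over the list alone, adjusted p = 0.0471, adjusted p = 0.392 with an estimated correlation), the B and plasma cell list (0 of 11, 6 adjusted over the list alone, adjusted p = 0.0496, adjusted p = 0.392 with an estimated correlation) and the interferon and receptor list (0 of 12, 0 adjusted over the list alone, adjusted p = 0.0496, adjusted p = 0.642 with an estimated correlation). Of these 5 calls only that of the class II list held under both scalings, and it was lost without on-doxycycline replicates 2 or 4 (0.067 and 0.0711) or AAV-hSPBTLR9i single replicate 2 (0.0508). Both gene calls were lost under both scalings and without each of on-doxycycline replicates 1, 2 and 4 and AAV-hSPBTLR9i single replicates 1, 2 and 4 (adjusted p from 0.0664 to 0.143). Each of the other 4 list calls was lost without on-doxycycline replicates 2 or 4 or AAV-hSPBTLR9i single replicates 1 or 2, with adjusted p from 0.0764 to 0.214. The interferon and receptor and the B and plasma cell calls were also lost without on-doxycycline replicate 1 (0.0719 and 0.0775), these and the interferon-gamma-inducible call without AAV-hSPBTLR9i single replicate 3 (0.0908 each), the interferon and receptor call without on-doxycycline replicate 3 (0.0734) and the B and plasma cell call without AAV-hSPBTLR9i single replicate 4 (0.0912). The count was 11 without on-doxycycline replicate 3 and 0 with the low or high series of a second lung identifier as a covariate.

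After a single AAV-hSPB dose limma called 0 genes against continued doxycycline (82 at an unadjusted p under 0.05, voom 3). The smallest p belonged to H2-DMa (0.69 ± 0.15, adjusted p = 0.0871), Cx3cr1, a chemokine receptor of monocytes and cytotoxic lymphocytes (0.91 ± 0.20, adjusted p = 0.0871), and Pik3ap1, a B cell signalling adaptor (0.40 ± 0.09, adjusted p = 0.0958). The MHC class II list rose on balance (0 of 10 called, 5 adjusted over the list alone, median 0.54, adjusted p = 0.0353, adjusted p = 0.239 with an estimated correlation). Its call was lost under both scalings (0.074 and 0.0752) and without on-doxycycline replicates 1, 2 or 4 (0.069, 0.146 and 0.194) or AAV-hSPB single replicates 3 or 4 (0.144 and 0.115). Without on-doxycycline replicate 3 limma called 11 genes, those 3 among them.

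The off-doxycycline lungs were compared with the on-doxycycline lungs, 3 days after doxycycline was withdrawn. These groups differ in doxycycline itself as well as in the transgene it drives. Sftpb was not analysed, so the loss of SP-B was not measured. No gene passed (limma 0 of 773, 96 at an unadjusted p under 0.05, voom 0). The smallest p belonged to Il17b (a log2 difference of at most -1.33, 9 to 13 recovered counts off doxycycline and not above background in those 4 lungs, adjusted p = 0.114), Il23a (adjusted p = 0.114) and H2-DMa (0.56 ± 0.15, adjusted p = 0.205). Il23a had a mean of 2.2 recovered counts on doxycycline. It was not above background in those 4 lungs or in 2 of 4 off doxycycline. With all of these raised to background the difference was 0.24, which is not a bound. The monocyte chemokine gene Ccl2 had a mean log2 level of 9.19 ± 1.84 (SD, n = 4) off and 6.49 ± 0.85 on doxycycline (adjusted p = 0.205), and Il6 had 6.22 ± 1.60 and 3.80 ± 0.75 (adjusted p = 0.277), with 3 of 4 on-doxycycline lungs not above background. The acute cytokine and chemokine list lay above 0 in 27 of 28 members (0 called, 5 adjusted over the list alone, median 0.58, adjusted p = 0.273). The count was 6 without off-doxycycline replicate 4 and 1 without on-doxycycline replicate 4, and 1, Il17b, with the identifier series as a covariate (adjusted p = 0.0252). The off-doxycycline lungs fell apart by sex, with Il1r2, a decoy receptor for interleukin-1, at 8.43 in the 2 female and 3.60 in the 2 male lungs, 1 of which was not above background.

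**Figure D4:**
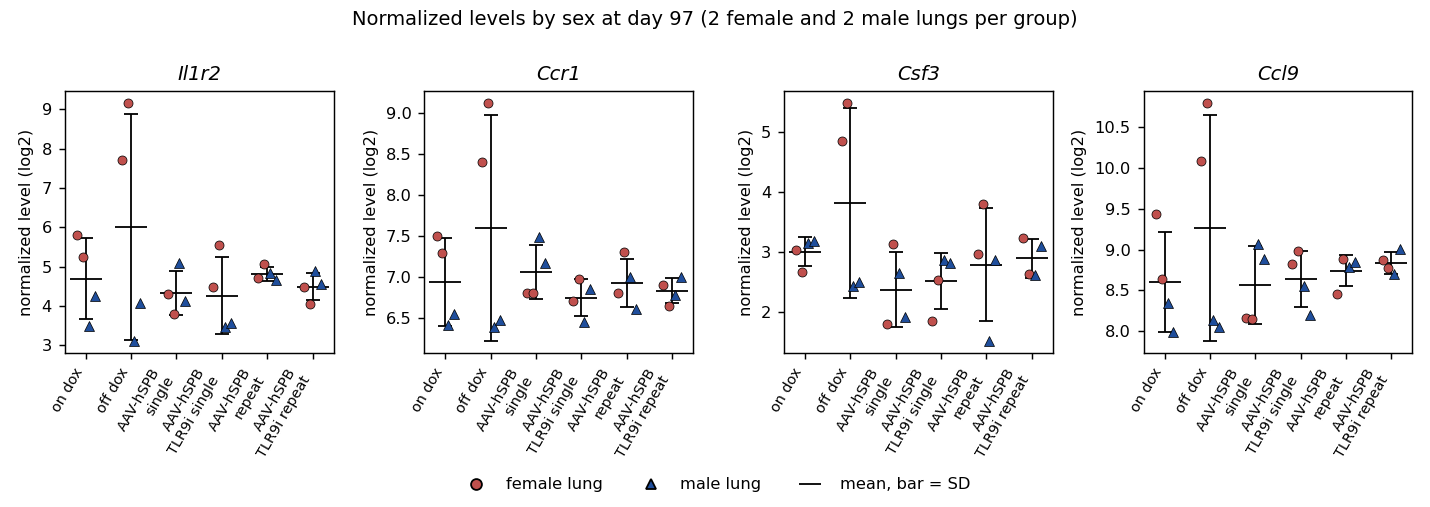
Normalized log2 levels (vertical axis) of 4 genes, chosen after their values were seen, in each day 97 lung, by group (horizontal axis); red circles are female and blue triangles male lungs, and the bar gives the mean and SD of 4 lungs. Off doxycycline, Ccr1 lay at 8.76 in the 2 female and 6.44 in the 2 male lungs, and Csf3 at 5.17 and 2.46, the latter not above background.

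Both single-dose vector groups together were set against the off-doxycycline lungs, to compare vector-treated lungs with lungs newly off doxycycline. The groups also differ in time off doxycycline, which was withdrawn at day 7 in the vector groups and at day 94 in the other. The B cell signalling adaptor gene Pik3ap1 (0.40 ± 0.08, adjusted p = 0.032) and the kinase gene Mknk1 (0.45 ± 0.09, adjusted p = 0.032) were higher after vector (n = 8 and 4), and limma called 3 genes higher and 0 lower (183 at an unadjusted p under 0.05, voom 1). Ccl2 had a log2 difference of -2.35 ± 0.64 and Cd79a of 0.90 ± 0.26 (each with adjusted p = 0.0728). The interferon and receptor list rose on balance (0 of 12 called, 0 adjusted over the list alone, median 0.16, adjusted p = 0.0174, adjusted p = 0.603 with an estimated correlation). That call was lost under both scalings (0.449 and 0.0995) and without off-doxycycline replicates 1 or 2 (0.135 and 0.131). Pik3ap1 and Mknk1 lost their calls on the median gene (adjusted p = 0.0985 for each). The gene count was 0 under both scalings, 95 without off-doxycycline replicate 4, 40 without off-doxycycline replicate 3, and 0 without off-doxycycline replicates 1 or 2, AAV-hSPB single replicates 1 or 2 or AAV-hSPBTLR9i single replicates 1, 3 or 4.

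At 3 h after the dose neither vector was told apart from PBS. Limma called 0 genes for AAV-hSPB (17 at an unadjusted p under 0.05, voom 0) and 0 for AAV-hSPBTLR9i (15 at an unadjusted p under 0.05, voom 0), with 3 lungs per group. The smallest p for AAV-hSPB belonged to the fatty acid activating enzyme gene Acsl1 (-0.38 ± 0.11), the endothelial adhesion molecule gene Sele (0.54 ± 0.16) and the monocyte chemokine gene Ccl7 (0.70 ± 0.22), each with adjusted p = 0.996. For AAV-hSPBTLR9i it belonged to Csf2 (0.47 ± 0.13), Tnfsf9 (0.99 ± 0.29) and Ccr3 (-0.47 ± 0.15), each with adjusted p = 1. Ccl2 had a mean log2 level of 5.95 ± 0.30 (SD, n = 3) after PBS, 6.89 ± 0.63 after AAV-hSPB and 6.78 ± 0.39 after AAV-hSPBTLR9i. Ifnb1 had 2.63 ± 0.56, 3.09 ± 0.55 and 3.21 ± 0.38, with means of 6.7, 9.7 and 8.7 recovered counts, and Isg15 differed from PBS by -0.52 ± 0.33 and -0.41 ± 0.33.

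None of the 20 lists passed at 3 h. The acute cytokine and chemokine list had a median of 0.28 for AAV-hSPB (adjusted p = 0.831) and 0.21 for AAV-hSPBTLR9i (adjusted p = 0.86), and the interferon-stimulated list 0.02 and -0.02 (adjusted p = 0.926 for each). For AAV-hSPB the interferon-stimulated mean was -0.06, of the opposite sign to its median and test. AAV-hSPBTLR9i against AAV-hSPB gave 0 genes (12 at an unadjusted p under 0.05, voom 0), with the smallest p for Ccl1 (-0.69 ± 0.22), Ifna4 (0.87 ± 0.28) and Il13ra2 (0.87 ± 0.28), each with adjusted p = 1. After AAV-hSPB and AAV-hSPBTLR9i, Ifna4 had means of 8.3 and 12.7 recovered counts, Il13ra2 of 12.0 and 19.0 and Il23a of 10.7 and 4.0. Without AAV-hSPBTLR9i replicate 2 limma called Il23a, named here after its values were seen, in the comparison with PBS (-2.53, adjusted p = 0.0232) and in that between the vectors (-3.15, adjusted p = 0.00508). On simulated data of this design with 200 of 773 genes changed, 79.8% of changes of 1 log2 unit and 41.7% of changes of 0.5 were recovered. These shares need not hold where few genes change. Here 12 to 17 genes per comparison had an unadjusted p under 0.05, where chance gives 38.7.

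**Figure D5:**
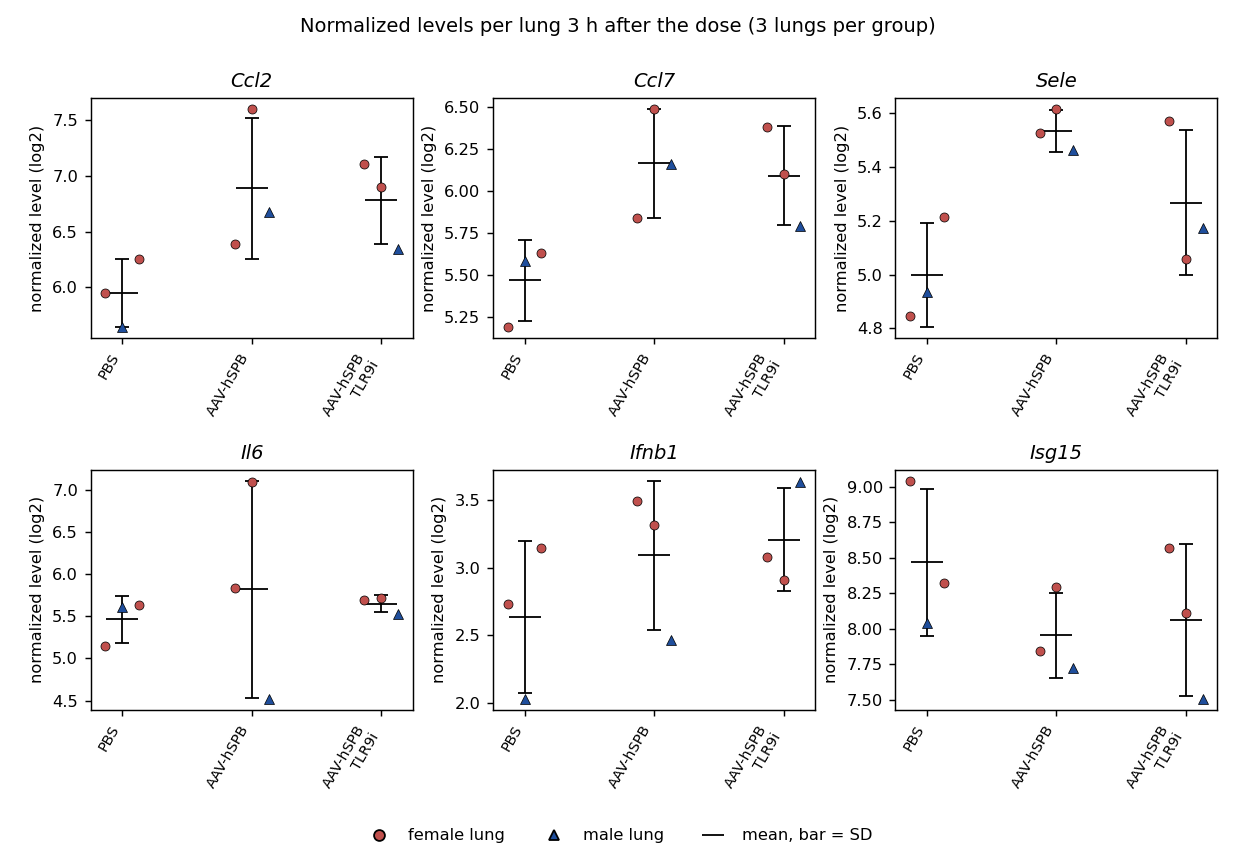
Normalized log2 levels (vertical axis) of 6 genes in each lung 3 h after the dose, by group (horizontal axis); red circles are female and blue triangles male lungs, and the bar gives the mean and SD of 3 lungs. Ccl2 averaged 5.95 after PBS, 6.89 after AAV-hSPB and 6.78 after AAV-hSPBTLR9i, and no gene passed the test.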

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

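The other splits of the lungs and the scalings to the median gene and to all 12 reference genes were fixed beforehand. What these scalings were asked about the patterns below, and all other tests in this part, were chosen only after the result was seen. The off-doxycycline lungs differed by sex. With 2 lungs of each sex, limma called 109 genes between female and male lungs off doxycycline, 68 higher and 41 lower in females, among them Ccr1 and Ccl9 (differences of 2.33 ± 0.24 and 2.35 ± 0.26 log2 units, SE), Il1r2 (4.15 with 1 male lung raised to background) and Csf3 (at least 0.94, not above background in the male lungs). Of the 3 ways to pair those 4 lungs only 1, the pairing by sex, called any gene, the other pairings giving at most 0, and 3 pairings are too few for a p-value. Scaling is an unlikely source, since 134 genes were called after each lung was re-centred on its median gene. Whether sex itself gives such a difference in other groups is open: the other 5 groups each gave 0 genes, but 2 against 2 lungs do not show absence, and the neutrophil list was 1.21 higher in females on doxycycline as well (fry adjusted p = 0.0169). A response to doxycycline withdrawal or SP-B loss that differs by sex, or by anything else that set these 2 female lungs apart, remains a hypothesis. These values do not settle it.

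A difference between the sexes in a comparison, tested as an interaction by limma, was seen for the genes given here and 1 list. There were 2 lungs per sex and group (4 per sex for both vectors together). The interaction does not tell a sex difference of the vector lungs from one of the control lungs. Between the sexes 109 genes differed off doxycycline, and 0 on doxycycline or in either single-dose group. For a single AAV-hSPB dose against doxycycline, Tnfrsf25 had an effect of 0.54 in females and -0.72 in males (difference 1.26), and the neutrophil list had means of -0.95 and 0.51 (adjusted p = 0.0308). That list had a female minus male difference of 1.21 on doxycycline and -0.25 after the single dose. Against the same on-doxycycline lungs it had -1.09 and 0.11 after the AAV-hSPB repeat (adjusted p = 0.159 in the same test). After the AAV-hSPBTLR9i repeat it had -1.10 and 0.28 (0.0528), after the single AAV-hSPBTLR9i dose -0.57 and -0.03 (0.605), and off doxycycline 0.07 and 0.19 (0.862). For both single-dose vectors against off doxycycline, Il1r2 had -3.90 in females and 0.46 in males (difference -4.36), Csf3 -2.85 and 0.09 (-2.94), Ccl9 -1.91 and 0.58 (-2.50), Ccr1 -1.94 and 0.56 (-2.49), Hlx 0.84 and -0.57 (1.41) and Tnfrsf25 0.83 and -0.18 (1.02). The values for Csf3 and Il1r2 are not exact. Csf3 was not above background in the male lungs off doxycycline or in any vector lung, so its female effect is only bounded, at most -0.98, and its male effect and the difference have no size. Il1r2 was not above background in 1 of 2 male lungs off doxycycline and in 2 of 4 female and 3 of 4 male vector lungs, and had -3.77 in females and 0.07 in males with these raised to background.

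In 10 of 126 groups of 4 values tested, 120 of list levels and 6 of total counts, 1 lung lay far from the other 3, where chance gives about 1 in 20, or 6.3. All 10 were list levels, and values are mean log2 levels less the on-doxycycline mean. AAV-hSPB single replicate 2 had 0.61 for MHC class I (others 0.09 to 0.14), 0.28 for NF-kB targets (0.02 to 0.06) and 0.51 for acute cytokines (0.12 to 0.17). AAV-hSPB single replicate 3 had 0.42 for interferon-stimulated genes (0.04 to 0.06) and 0.10 for type 2 immunity (0.02 to 0.03). Acute cytokines stood at 1.25 in AAV-hSPBTLR9i single replicate 2 (-0.03 to 0.16) and 0.75 in AAV-hSPBTLR9i repeat replicate 1 (0.37 to 0.43). The remaining values were 0.70 for CD8 T, NK and cytotoxic cells in AAV-hSPBTLR9i single replicate 1 (0.24 to 0.29), 0.69 for monocytes and macrophages in AAV-hSPB repeat replicate 2 (0.24 to 0.25) and -0.17 for inflammasome and cell death genes in on-doxycycline replicate 4 (0.04 to 0.08).

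Of the 6 reference genes left out of the authors' scaling, used here only in the alternatives with all 12, 3 stood above the on-doxycycline lungs in some groups. Stk11ip had a mean log2 level of 6.77 on doxycycline and was 0.33 higher after a single AAV-hSPBTLR9i dose, 0.86 after the AAV-hSPB repeat and 0.57 after the AAV-hSPBTLR9i repeat. Gusb was 0.42 higher after the AAV-hSPB repeat (10.28 against 9.86) and Nrde2 0.58 higher after the AAV-hSPBTLR9i repeat (6.95 against 6.37). Each of these had exact permutation p = 0.0286, unadjusted, the smallest that 4 against 4 lungs allow. Alas1 lay the other way in all 5 groups, with differences from -0.30 to -0.61 (smallest exact permutation p = 0.0571).

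The rise of the interferon-gamma-inducible and MHC class I lists after a second AAV-hSPB dose was weighed against 2 technical explanations. Repeat and single AAV-hSPB lungs lie in different blocks of the sample numbering, 1 to 12 and 13 to 24. AAV-hSPB repeat against the AAV-hSPBTLR9i single lungs of its own block called 48 genes, 45 higher and 3 lower. Of these 39 were among the 56 of the main comparison, an overlap that the AAV-hSPB repeat lungs shared by both comparisons favour. The 2 single-dose groups, which lie in different blocks, differed in 0 genes. In both checks the vector differs as well. AAV-hSPBTLR9i repeat against single, within 1 block, called 3 genes, 2 of them among the 56, and had the same sign in 56 of 56. These values make the blocks alone a less likely source but do not exclude them. The choice of reference genes is also unlikely, since of 16 list members called higher, of 22 measured, 15 were still called with all 12 reference genes and 16 with the median gene. A response of the lung to the second dose of vector remains as a hypothesis. These groups cannot tell it apart from a response to recent dosing.

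On-doxycycline replicate 1 held liver transcripts, with Plg at 11.39 (2.71 to 4.25 in the other 23 lungs), Serpina1a at 15.41 (8.20 to 9.63), Crp at 9.42 (1.15 to 3.49) and H2-Q10 at 11.09 (3.28 to 4.97). Liver RNA in the library could account for this, since 2 of 2 other liver-enriched genes, Ephx2 among them, were highest there. An acute-phase response of the lung is less likely, since the acute cytokine level of this lung was 0.13 and another on-doxycycline lung reached 0.42. Library depth is an unlikely source at a count of 720119, inside the range of the other lungs.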

How the results depend on the processing

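The other splits of the lungs were fixed beforehand. Voom, the omission of on-doxycycline replicate 1 with AAV-hSPB repeat replicate 2 or of PBS replicate 1, the list test with 12 reference genes and the identifier covariate were chosen after seeing the data. Of the counts under an alternative 227 stayed within 1.5 times the main value and 60 did not. The 227 include counts where neither fit called a gene, and a count that stayed need not hold the same genes. Lists kept their call in 322 cases, lost it in 115 and turned in 4. Named genes had the same status, called or not called, in 1866 cases, which include genes called in neither fit. Named genes lost a call in 110 cases, gained a call in 25 and turned in 5. The cause was not tested for any of these.

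Counts that moved were, for off against on doxycycline, 1 on the median gene. For single AAV-hSPB against doxycycline they were 3 by voom and 1 without the 2 doubted lungs, on-doxycycline replicate 1 and AAV-hSPB repeat replicate 2. For single AAV-hSPBTLR9i, 2 became 0 on the median gene, with all 12 reference genes, with the series matrix and with the compared groups alone, 9 without the lowest 25% of genes, 7 with sex as a covariate and 7 without the doubted lungs. For both single-dose vectors against off doxycycline, 3 became 0 under the first 3 of these, 5 without the lowest 25%, 10 with sex, 1 with a trended prior, 1 by voom and 39 without the doubted lungs. With the compared groups alone AAV-hSPB repeat gave 84 against doxycycline and 12 against single, and AAV-hSPBTLR9i repeat against single gave 14, and 1 with all 12 reference genes or the series matrix. List calls numbered 34, with all 12 reference genes 19, and by camera 0.

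Without each lung in turn the counts ran from 0 to 6 for off against on doxycycline, 0 to 11 for each single dose, 142 to 228 for AAV-hSPB repeat, 57 to 111 for AAV-hSPBTLR9i repeat, 0 to 95 for vectors against off doxycycline, 28 to 70 and 0 to 3 for repeat against single AAV-hSPB and AAV-hSPBTLR9i, 0 to 0 between the vectors at each dose, 0 to 1 for the interaction, 0 to 0, 0 to 1 and 0 to 1 at 3 h, and 26 to 40 for list calls. The interferon and receptor list turned after AAV-hSPB repeat on the median gene (adjusted p = 0.469) and by camera (0.981) and after AAV-hSPBTLR9i repeat on the median gene (0.89), and the sensing list after AAV-hSPB repeat on the median gene (0.799). After AAV-hSPB repeat H2-Q10 turned to 0.136 without both doubted lungs and ran from -2.503 to 0.034 without each lung in turn, turning without on-doxycycline replicate 1. Ifit1 ran from -0.184 to 0.081, turning without on-doxycycline replicates 1 or 2 or AAV-hSPB repeat replicate 1.

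Of 35 splits of the 8 lungs, 1, the real one, gave as many genes for single AAV-hSPBTLR9i (2, highest other 0), AAV-hSPB repeat (180 higher and 23 lower, other 68 in all), AAV-hSPBTLR9i repeat (89, other 1), AAV-hSPB repeat against single (56, other 14) and AAV-hSPBTLR9i repeat against single (3, other 0). Where the real split gave 0 genes, every split must give as many, so the share of splits tests nothing. That held, with 35 of 35, for off against on doxycycline (0, other 27, which points to a structure of the samples), single AAV-hSPB (0, other 0) and the vectors after single (0, other 0) and repeat dose (0, other 1). It held for the interaction too, with 100 of 100 (0, other 16). For both vectors against off doxycycline 3 of 100 splits gave as many genes (3, other 21). In these last 2 comparisons splits also mix lungs of different treatment, and no structure was tested. At 3 h the 10 splits are too few, with 0 real and 0, 0 and 2 as the highest other.

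No paired analysis was possible because the groups share no replicate number. Each day 97 lung has a running title number and, in the authors' table, a second identifier of its own, whose meaning is not given in the sources used here. In 2 runs of 4 vector lungs with consecutive identifiers, deviations from the group means correlated at -0.24 to 0.35 and -0.08 to 0.17. With the low or high series of this identifier as a covariate the count was 1 for off against on doxycycline and 0 for single AAV-hSPBTLR9i, and no other count moved by over 1.5 times. Reference-gene scaling was not run for the 3 h table, the series matrix values were not usable at 3 h, and a pseudocount did not apply to values already in log2. Depth limits genes under 20 counts, 65 to 117 per day 97 lung.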

Other observations

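All values in this part were chosen only after they were seen. The 2 female and the 2 male lungs off doxycycline differed in single genes, of which those given here were picked after they were seen. Lcn2, an iron-sequestering protein, averaged 15.13 in the female and 11.42 in the male lungs (difference 3.71 ± 0.78 log2 units, SE, limma adjusted p = 0.00813). Cd14, a co-receptor for endotoxin, differed by 2.36 ± 0.34 (adjusted p = 0.00147), Cxcl3, a neutrophil chemokine, by at least 1.61 (not above background in the male lungs) and Fcgr2b, an inhibitory antibody receptor, by 3.16 ± 0.61. Ackr4, a scavenging chemokine receptor, had a difference of at most -3.18, not being above background in the female lungs. Tnfsf10, which encodes the death ligand TRAIL, was lower in the female lungs, with -1.80 ± 0.36, as was Ifit3 with -1.21 ± 0.23. The monocyte and macrophage list had a mean difference of 1.00 (fry adjusted p = 0.00475), though its members Csf1r (-0.04 ± 0.17, adjusted p = 0.906), Lyz2 (-0.05 ± 0.25, 0.916) and Ccr2 (0.66 ± 0.28, 0.13) did not pass. Neutrophils had 1.09 (0.0195), inflammasome and cell death genes 0.31 (0.0195) and acute cytokines 1.35 (0.0222). The neutrophil difference was also present on doxycycline, 1.21 higher in the 2 female lungs (0.0169), where monocytes and macrophages had 0.20 (0.768), inflammasome and cell death genes 0.14 (0.666) and acute cytokines -0.11 (0.995). Off against on doxycycline, limma called 100 genes in females, 58 higher and 42 lower (244 at an unadjusted p under 0.05), and 0 in males (15 at an unadjusted p under 0.05), with n = 2 per group. These counts do not test a difference between the sexes. The interaction, which does, called 1 gene, not named here, and no list (smallest list adjusted p = 0.258). On-doxycycline replicate 1, the lung with high liver transcripts, was 1 of the 2 female lungs on doxycycline.

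PBS replicate 1 at 3 h stood apart in a cluster of granzyme genes, with Gzmd at 10.25 (2.89 to 4.42 in the other 8 lungs), Gzmg at 10.30 (3.99 to 4.74), Gzmf at 9.89 (4.49 to 5.25), Gzme at 8.60 (3.35 to 4.68) and Gzmc at 7.74 (3.69 to 5.03).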
